A study of Mus musculus with 36 samples.

How the data were processed

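Gene expression was measured with Affymetrix Mouse Genome 430 2.0 arrays, 1 RNA sample per array, in the left ventricle of 36 mouse hearts. Per the labels, 3 transgenic lines carry a floxed HRas-v12, MKK3bE or MKK7D transgene behind the cardiac alpha myosin heavy chain promoter. Each was crossed to a line with Mer-Cre-Mer, a Cre recombinase fused to modified estrogen receptor parts that tamoxifen activates, driven by the same promoter. Double transgenic mice and littermates without transgenes received tamoxifen at 20 mg/kg on 3 consecutive days at 12 weeks of age. The early time point lay 4 to 7 days after the first injection and the late time point 2 to 4 weeks after it.

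The deposited values are probe set signals of unit intensity on a linear scale, made with MAS5 per the submitters' processing notes, and the version is not given in the sources used here. Every array had the same mean signal of 2500 once 2% of the probe sets were left off at each end, so 1 factor per array had been applied before deposit. Signals ran from 0.4 to 271532.1, and the median per array from 593.5 to 798.6. Detection calls were not used here, so a low signal carries no statement on presence. Of 45101 probe sets, 34958 were paired with 1 gene symbol, 932 with several and 9211 with none in the annotation table used. Of the first kind, 34754 were updated to the current symbol through the gene number. Probe sets with several symbols or none named no gene, and the 64 Affymetrix control probe sets stayed out of all tests. Probe sets of Hras and Map2k7 were not named in that table, and both genes were not analysed here.

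Values were taken as log2(signal + 32), with no further scaling between arrays. Probe sets in the upper 60% by mean log2 value over the 36 arrays were kept, which meant a mean of at least 8.802 (a signal of about 414.3). This left 27022 probe sets, and the brightest probe set of each gene gave 12626 genes tested. Fold changes are on the log2(signal + 32) scale and understate the change of dim genes. A linear model with 13 group means was fitted over all 36 arrays in limma 3.58.1 under R 4.3.3, with eBayes and an intensity trend (23 residual degrees of freedom, 4.61 prior degrees of freedom). Groups of 2 or 3 arrays thus shared 1 estimate of the spread. Where both sexes were present, a change is the mean of the female and the male difference. Adjusted p-values are Benjamini-Hochberg values over the genes tested, and a gene was called under 0.05. All p-values with an n under 10 are such adjusted p-values from limma. The labels number the arrays as replicates without saying that each is a separate animal, so p-values measure only the spread between these arrays, whose number limits the precision.

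Groups came from the array titles. Control males and control females, 3 arrays each, carry no time point in the labels and served both times of the HRas-v12 and MKK3bE lines. The MKK7D line had its own female controls at each time. There were 16 comparisons: 6 of a line at a time against its control, 3 between times, 3 between lines and 4 between sexes.

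The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, in each comparison against control, the 10 genes with the largest rise and the 10 with the largest fall among those called. It kept only genes with 1 symbol that is no clone or model name and with every transgenic array on the same side of the mean of its sex-matched control arrays. It added up to 4 members with the smallest adjusted p of each fixed list that passed its test or had a member called, and Hras, Map2k3 and Map2k7 always. Other genes are said where they stand to have been chosen after their values were seen. For differences between lines, times or sexes the first part of the rule was used without the check of each array. Of 359 called pairs of a named gene and a comparison, 196 had a further probe set above the filter, and 40 of these 372 further probe sets changed with the opposite sign.

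Lists of gene groups and of cell type markers were tested with camera in limma at a preset correlation of 0.01, and again with an estimated correlation. The 27 lists with at least 5 members tested entered. Lymphocyte, neutrophil, skeletal muscle and red blood cell marker lists had fewer and were not tested, and the sex-linked genes only checked the labels. With an estimated correlation 1 of the 107 list calls remained, so a list's call says that its members moved against the other genes of these arrays. Adjusted p-values of lists are over all lists and comparisons.

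Arrays were checked for quality. The 3 prime to 5 prime signal ratio was 0.788 to 0.899 for Gapdh and 0.977 to 1.53 for beta-actin. The 100 brightest probe sets held 6.079% to 9.735% of the signal. Correlations between arrays ran from 0.838 to 0.9782, and no 2 columns were identical.

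The fit was tested on simulated data with known changes in 200 genes. For early HRas-v12 against control it recovered 50.7% of genes changed 1.5-fold, 88.1% changed 2-fold and 98.5% changed 4-fold. At the same folds it recovered 53.7%, 76.1% and 98.5% for late HRas-v12, and 17.9%, 59.7% and 93.9% for early MKK3bE. The values were 31.3%, 70.1% and 95.5% for late MKK3bE, 25.4%, 67.2% and 97% for early MKK7D, and 32.8%, 47.8% and 98.5% for late MKK7D. For late against early HRas-v12 they were 44.8%, 76.1% and 100%, for late HRas-v12 against late MKK3bE 32.8%, 80.6% and 98.5%, and for late minus early MKK7D 5.97%, 47.8% and 78.8%. For the sex difference of the early HRas-v12 change it recovered 1.49%, 29.9% and 72.7%. A list shifted by 0.5 on the log2 scale was called in 20 of 20 runs simulated for late HRas-v12, with 5 calls of the 26 unshifted lists over all runs. Simulated genes varied independently of each other, so these runs cannot tell how often lists are called falsely where genes move together.

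Alternatives were quantile normalization, a pseudocount of 1, no filter, all probe sets, a fit on only the groups compared, a replicate block, camera with an estimated correlation, and leaving out each array in turn. A pseudocount of 160 and a fit without 6 arrays whose Esr1 or sex-linked signal goes against the label were added after the data had been seen. Overlaps of calls between comparisons that share controls were set beside 100 simulations of unchanged groups against the same controls. Gene order came from the GRCm38.p6 annotation and was used only to tell which genes neighbour each other.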

Results

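The series asked how the adult mouse heart responds when different mitogen-activated protein (MAP) kinase pathways are switched on in cardiac muscle cells. HRas-v12 is an always active form of the Ras switch protein that feeds the ERK pathway among others. MKK3bE is an active form of the kinase upstream of p38, and MKK7D of the kinase upstream of JNK. The 36 arrays fell into 13 groups of 2 or 3. HRas-v12 had 2 female and 3 male early arrays and 3 of each sex late. MKK3bE had 2 female early arrays, and 2 female and 3 male late arrays. MKK7D had 3 female arrays per time, with 3 female controls per time, and 3 male and 3 female control arrays served the other lines.

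The transgenes and the driver were looked at first. The brightest Esr1 probe set, which Mer-Cre-Mer RNA could also feed since Mer is a part of the estrogen receptor, read 294 to 7943 in the 6 shared control arrays, 5 of them under 1000. It lay above all of these, at 12437 to 155949, in 21 of the 24 transgenic arrays. The other 3 read 688 in the array labelled HRas-v12 female early replicate 3, 2915 in that labelled male late replicate 1 and 1327 in that labelled male late replicate 3. Of the late MKK7D controls, the arrays labelled replicate 8 and replicate 9 read 106402 and 91291, and replicate 10 read 953. The other 2 Esr1 probe sets stayed between 13 and 1296 in all arrays. Xist and Eif2s3y matched the labelled sex in 35 of 36 arrays. The array labelled MKK7D control female early replicate 1 had Xist at 2316 and Eif2s3y at 6018, as in males. Map2k3, the mouse gene of MKK3, changed by 0.14 on the log2 scale early (SE 0.19, limma adjusted p = 0.703) and 0.10 late (SE 0.13, adjusted p = 0.687) in the MKK3bE line. A probe set outside the part of the gene that a transgene carries cannot see it. Map2k3 changed by 0.57 in early HRas-v12 hearts (SE 0.13, adjusted p = 0.00166, and 0.0509 without female early replicate 1). A further Map2k3 probe set stood at 1.15 in these hearts.

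**Figure D1:**
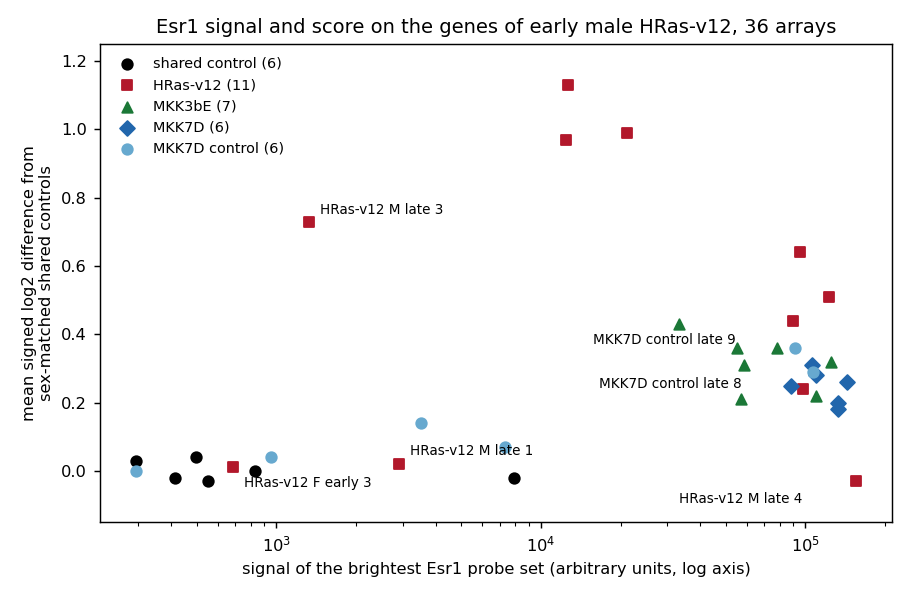
Signal of the brightest Esr1 probe set (arbitrary intensity units, log axis) against the mean signed log2 difference from the sex-matched shared controls over the 4816 genes called in early male HRas-v12 hearts (the score of an array), with 1 point per array for the 36 arrays. The 6 shared controls lie between -0.03 and 0.04 on the vertical axis and the early male HRas-v12 arrays between 0.97 and 1.13. The genes were chosen in those early males against control males. The shared controls of each sex are the reference, so both ranges are partly set by these choices.

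Early HRas-v12 hearts built up extracellular matrix and cell cycle transcripts and lost those of energy metabolism and contraction. Tnc, the matrix glycoprotein tenascin-C, was 32.4-fold higher (log2 change 5.02, SE 0.69, limma adjusted p = 2.19e-05), with a signal of 32520 ± 25945 (SD, n = 5) against 393 ± 281 (SD, n = 6) in controls. Dusp5, a phosphatase that acts on ERK and is made in response to it, was 13.9-fold higher (log2 change 3.80, SE 0.80, adjusted p = 0.000829). Kcnip2, a subunit of the channel of the transient outward potassium current, was 15.2-fold lower (log2 change -3.93, SE 0.49, adjusted p = 8.2e-06). Further Kcnip2 probe sets stood at -2.94 and -0.82 on the log2 scale. The log2 changes of Tnc, Dusp5 and Kcnip2 were 3.56, 2.55 and -3.29 without female early replicate 1 and 6.47, 5.05 and -4.56 without female early replicate 3. Of 12626 genes tested, 4267 were called, 1903 higher and 2364 lower, and 851 of them changed at least 2-fold.

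The genes with the largest rises after Tnc were Lcn2, Dusp5, Timp1, Cthrc1, Lox, Egr3, Anln, Alcam and Pdk3. Timp1, an inhibitor of matrix-degrading enzymes, was 13.5-fold higher, Cthrc1 10.2-fold and Lox, which cross-links collagen, 9.14-fold. The largest falls after Kcnip2 were Dhrs7c, Klf15, Rasl10b, Prkcq, Lgi1, Ces1d, Lrtm1, Fbp2 and Fam120c. Klf15, a transcription factor of fuel metabolism in heart muscle, was 8.08-fold lower. Timp1, Cthrc1 and Lox stood at 3.76, 3.36 and 3.19 on the log2 scale, at 2.55, 2.51 and 2.52 without female early replicate 1 and at 4.96, 4.20 and 3.87 without replicate 3. The calls of Lgi1 and Fbp2 ended without replicate 1 (adjusted p = 0.0677 and 0.0896). A further probe set of Egr3 stood at -0.13 on the log2 scale.

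Among extracellular matrix and fibrosis genes, 29 of 33 tested rose and none fell (29 adjusted over the list alone, median log2 change 1.34). The list stood apart from other genes (camera adjusted p = 3.57e-15, and adjusted p = 0.578 with an estimated correlation). Of 22 cell cycle genes 18 rose (19 over the list alone, camera adjusted p = 1.7e-09, adjusted p = 0.578 with an estimated correlation), with Birc5 5.32-fold and Ube2c 4.89-fold higher. Cdkn1a, an inhibitor of the cell cycle counted in the same list, was 4.49-fold higher. Of 15 ERK pathway feedback and target genes 10 rose (10 over the list alone, adjusted p = 9.07e-06, and 0.591 as adjusted p with an estimated correlation), among them Spred1 at 4.53-fold and Spry4 at 3.50-fold. Macrophage markers rose in 10 of 18 members (11 over the list alone, adjusted p = 1.24e-05, adjusted p = 0.644 with an estimated correlation), with Cd52 3.04-fold and Cd68 2.45-fold higher. Endothelial cell markers fell in 12 of 15 members (12 over the list alone, adjusted p = 1.64e-05, adjusted p = 0.578 with an estimated correlation), with Kdr 2.12-fold lower. Without female early replicate 1 the log2 changes of Birc5, Spred1 and Spry4 were 1.65, 1.52 and 1.07, and without replicate 3 they were 3.18, 2.84 and 2.55. The calls of Cd52 and Cd68 ended without replicate 1 (adjusted p = 0.147 and 0.0849).

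Respiratory chain and ATP synthase genes fell in 40 of 41 members (40 adjusted over the list alone, median log2 change -0.55, camera adjusted p = 6.69e-13, adjusted p = 0.621 with an estimated correlation). Fatty acid oxidation genes fell in 23 of 28 members (26 over the list alone, adjusted p = 1.04e-10, adjusted p = 0.591 with an estimated correlation), and Fabp3, which binds fatty acids in muscle, was 2.46-fold lower. Citric acid cycle genes fell in 19 of 20 (20 over the list alone, adjusted p = 3.3e-08, adjusted p = 0.621 with an estimated correlation). Sarcomere genes fell in 18 of 21 (19 over the list alone, adjusted p = 6.34e-10, adjusted p = 0.578 with an estimated correlation), and the Z-disc gene Tcap was 4.01-fold lower. Quantile normalization moved the sarcomere median from -0.55 to -0.18 and the respiratory chain median to -0.27, both still called. Calcium handling genes fell in 12 of 17 (12 over the list alone, adjusted p = 0.000234) and potassium and sodium channel genes in 10 of 17 (11 over the list alone, adjusted p = 0.000665). Their adjusted p-values with an estimated correlation were 0.578 and 0.621. Of 11 hypertrophy marker genes 4 rose and 1 fell (5 and 1 over the list alone, adjusted p = 0.0188, adjusted p = 0.654 with an estimated correlation), with Rcan1 2.12-fold and Xirp1 1.62-fold higher. Rcan1 was no longer called without female early replicate 1 (adjusted p = 0.135). Acta1, a marker on the same list, went the other way. Its mean signal was 35630 in males against 101345 in control males. In females it was 30631 against 55342, while early female MKK3bE hearts had a mean of 148523.

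Of the 5 early arrays, the array labelled female replicate 3 had Esr1 at the control level, and 5335 genes were called without the 6 arrays in doubt, a fit added after the data had been seen that leaves 1 early female array. Without female early replicate 1 the count was 1571.

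**Figure D2:**
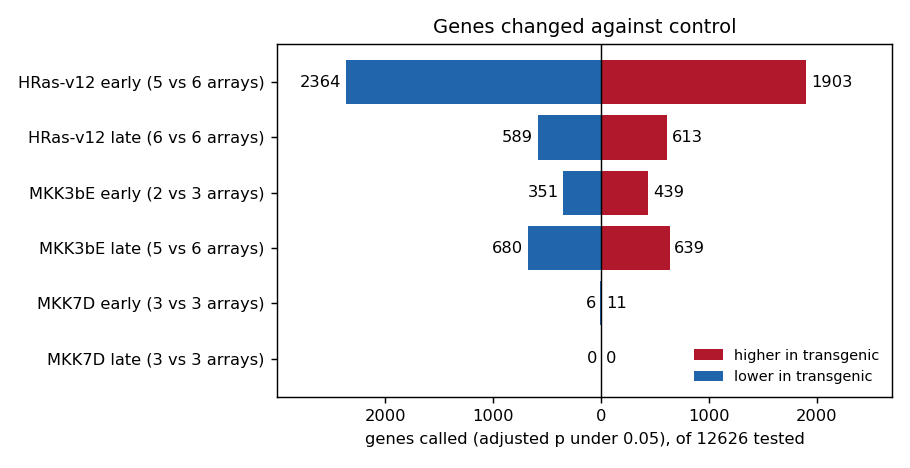
Number of genes called higher (right) and lower (left) in each line and time against its control at an adjusted p under 0.05, of 12626 genes tested, with the arrays on each side in brackets. Early HRas-v12 had 1903 genes higher and 2364 lower, and late MKK7D had none.

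Late HRas-v12 hearts held more matrix transcripts and fewer of the respiratory chain than controls. Thbs1, the matrix protein thrombospondin-1, was 5.08-fold higher (log2 change 2.34, SE 0.48, limma adjusted p = 0.0129), with a signal of 5798 ± 4316 (SD, n = 6) against 873 ± 337 (SD, n = 6). Gnai1, an inhibitory G protein subunit, was 3.97-fold higher (log2 change 1.99, SE 0.31, adjusted p = 0.00233). The brightest probe set of Asph, which encodes junctin of the calcium release unit among other products, was 2.14-fold lower (log2 change -1.10, SE 0.22, adjusted p = 0.0129). Of the other 5 Asph probe sets 1 stood at -0.95 and 4 at 0.02 to 0.32. In all 1202 genes were called, 613 higher and 589 lower, 157 of them by at least 2-fold.

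The largest rise was Esr1, the driver-related probe set, followed by Mfap4, Thbs1, Ecrg4, Serpinb1a, Gnai1, Slc16a3, Sardh, Ncam1 and Cd276. The largest falls were B3galt5, Prkag3, Rasl10b, Thrsp, Fam120c, Cryba4, Epha4, Syt7, Rab30 and Asph. B3galt5 was 3.36-fold lower, and Prkag3, a subunit of the energy sensor AMPK, 3.33-fold. Without male late replicate 3 the calls of Mfap4, Ecrg4, Slc16a3, Ncam1, Prkag3, Rasl10b, Cryba4, Epha4 and Syt7 ended (adjusted p from 0.0506 for Prkag3 to 0.132 for Cryba4), and without female late replicate 3 also that of Fam120c (0.0989). The other 3 probe sets of Syt7 stood at 0.05, -0.77 and 0.23, and a further probe set of B3galt5 at -0.29.

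Extracellular matrix and fibrosis genes rose in 22 of 33 members (30 adjusted over the list alone, median log2 change 0.99, camera adjusted p = 7.8e-15, adjusted p = 0.578 with an estimated correlation), with Mmp2 and Col6a1 both 1.99-fold higher. ERK pathway feedback and target genes rose in 6 of 15 (11 over the list alone, adjusted p = 2.52e-05, adjusted p = 0.591 with an estimated correlation), among them Dusp4 at 3.67-fold and Spred1 at 3.03-fold. Respiratory chain and ATP synthase genes fell in 35 of 41 (41 over the list alone, median -0.49, adjusted p = 5.94e-24, adjusted p = 0.578 with an estimated correlation), with Uqcrc2 1.64-fold lower. Fatty acid oxidation genes fell in 12 of 28 (26 over the list alone, adjusted p = 2.72e-12, adjusted p = 0.591 with an estimated correlation). Sarcomere genes fell in 12 of 21 (17 over the list alone, median -0.37, adjusted p = 1.7e-09, adjusted p = 0.578 with an estimated correlation), but under quantile normalization their median was -0.04 and the list was no longer called (adjusted p = 0.51). Glycolysis genes, 3 of 18 up and 3 down (3 and 11 over the list alone, adjusted p = 0.0223, adjusted p = 0.621 with an estimated correlation), had a median of -0.25 that moved to -0.02 under quantile normalization, with the direction of the list turned. No cell cycle gene was called (0 of 22 and 0 over the list alone in limma), while the list as a whole had a median of 0.52 (camera adjusted p = 0.00393, adjusted p = 0.715 with an estimated correlation). Fibroblast markers rose in 4 of 15 members (7 over the list alone, adjusted p = 0.00303, adjusted p = 0.644 with an estimated correlation), with Mgp 1.76-fold higher. Of 18 macrophage markers 2 rose, Cd52 and C1qb, and 1 fell, Cd163 (4 and 1 over the list alone, adjusted p = 0.00111, adjusted p = 0.715 with an estimated correlation). Without male late replicate 3 the calls of Mmp2, Col6a1, Dusp4, Mgp, Cd52, C1qb and Cd163 ended (limma adjusted p = 0.055, 0.0773, 0.117, 0.133, 0.15, 0.158 and 0.0989).

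The late means include male replicate 1 (score 0.02) and male replicate 4 as well as 4 arrays that scored 0.24 to 0.73. A fit on only the groups compared called 0 genes in limma, with 2668 at an unadjusted p under 0.05, and 157 were called without the 6 arrays in doubt, which leaves in the male arm replicate 4 alone, an array that scored like a control (-0.03). That fit had 8 of 33 matrix genes higher, 11 of 41 respiratory chain genes lower and the cell cycle, macrophage and channel lists no longer called. Leaving out 1 HRas-v12 array gave 132 (male replicate 3), 170 (female replicate 3), 630 (female replicate 4) or 2507 (male replicate 4), and leaving out 1 control gave 485 (female replicate 1), 526 (male replicate 1), 777 (male replicate 2) or 788 (male replicate 5).

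Set directly against early HRas-v12 hearts, late hearts had lower Lcn2, Cthrc1, Tnc and Lox and higher Kcnip2 and Klf15. The gene lists were not tested between the times. The means include arrays at the control level of the score, late male replicates 1 and 4 (0.02 and -0.03) and early female replicate 3 (0.01). Lcn2, the iron-binding protein lipocalin-2, was 16.4-fold lower late (log2 change -4.03, SE 0.56, limma adjusted p = 7.21e-05), with mean signals of 1045 late and 23281 early. Cthrc1 was 6.79-fold, Tnc 6.58-fold and Lox 5.46-fold lower. Kcnip2 was 6.95-fold higher late (adjusted p = 0.000693), Klf15 5-fold and H2-Aa, which presents antigen on immune cells, 5-fold. In all 1463 genes differed, 873 higher and 590 lower late. The count was 49 in a fit on only these groups and 3291 without the 6 arrays in doubt, which leaves 1 early female and 1 late male array. Without 1 array it was 338 (female early replicate 1), 861 (male early replicate 1), 865 (male late replicate 1), 893 (female late replicate 2), 2270 (female early replicate 3) or 2716 (male late replicate 3).

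The early HRas-v12 change was compared between the sexes. It differed in 139 genes, 37 more positive and 102 more negative in males. Kcnip2 differed by -5.16 on the log2 scale (SE 0.97, limma adjusted p = 0.0154), and Art1 by -3.08 (SE 0.44, adjusted p = 0.00164). Slc6a19, an amino acid transporter, differed by 3.61 (SE 0.62, adjusted p = 0.00598). The 2 female early arrays differed in their Esr1 signal, 95274 in replicate 1 and 688 in the array labelled replicate 3. The count was 4 without replicate 3 and 1393 without replicate 1, 81 without the 6 arrays in doubt and 29 in a fit on only the groups compared. It was 19 and 237 without male early replicates 1 and 3. It was 39 and 41 without control females 4 and 1, and 86, 54 and 61 without control males 1, 2 and 5. Late, limma called 0 genes between the sexes, with 988 at an unadjusted p under 0.05, and 5 were called without male late replicate 3. Without the 6 arrays in doubt 476 were called, but the male late arm is then replicate 4 alone, which scored like a control (-0.03).

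Early MKK3bE hearts, all female, raised hypertrophy markers, matrix genes and some heat shock protein genes. Ankrd2, a stretch-responsive muscle gene, was 15.4-fold higher (log2 change 3.94, SE 0.84, limma adjusted p = 0.00685). Shisa3 was 36.1-fold higher (log2 change 5.18, SE 0.66, adjusted p = 6.22e-05), at 17372 ± 3170 (SD, n = 2) against 453 ± 96 (SD, n = 3). Hspa1b, an inducible chaperone of the Hsp70 family, was 6.57-fold higher (log2 change 2.71, SE 0.56, adjusted p = 0.0051). Mylk4, a myosin light chain kinase gene, was 19.8-fold lower (log2 change -4.31, SE 0.67, adjusted p = 0.000459), at 2171 ± 811 (SD, n = 2) against 42090 ± 1880 (SD, n = 3). Without replicate 2 the calls of Ankrd2 (log2 change 3.15, adjusted p = 0.132) and Hspa1b (2.64, 0.068) ended. In all 790 genes were called, 439 higher and 351 lower, and 427 changed at least 2-fold.

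The largest rises were Shisa3, Muc15, Serpinb1a, Mfap4, Syndig1, Krt18, Nmrk2, Ankrd2, Chodl and Star. Star, which carries cholesterol into mitochondria for steroid synthesis, was 14.2-fold higher. The largest falls were Mylk4, Ces1d, Ybx2, Cenpf, Pla2g5, Rasl10b, Smco1, Hlf, Kcnv2 and Slc16a7. In the pathway the transgene feeds, Mapk14, the gene of p38 alpha, fell by 0.93 on the log2 scale in its brightest probe set (adjusted p = 0.000685; -1.25 to -0.03 in the other 5) and Map2k6, a further kinase upstream of p38, fell by 2.18 (adjusted p = 0.023). Mapk12, the gene of p38 gamma, rose by 0.83 (adjusted p = 0.00713). Without replicate 2, Map2k6 and Mapk12 were no longer called (adjusted p = 0.0723 and 0.0746). Of the rises listed Shisa3, Muc15, Serpinb1a, Krt18 and Star then stayed called, and of the falls Mylk4 and Pla2g5.

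Hypertrophy marker genes rose in 7 of 11 members (10 adjusted over the list alone, median log2 change 1.44, camera adjusted p = 1.94e-08, adjusted p = 0.37 with an estimated correlation), among them Rcan1 at 4.97-fold and Fhl1 at 3.01-fold. Extracellular matrix and fibrosis genes rose in 17 of 33 (29 over the list alone, adjusted p = 2.17e-18, adjusted p = 0.578 with an estimated correlation), with Thbs1 10.1-fold higher. Heat shock protein genes rose in 7 of 18 (7 over the list alone, adjusted p = 0.000666, adjusted p = 0.578 with an estimated correlation). Potassium and sodium channel genes fell in 3 of 17 (6 over the list alone, adjusted p = 1.25e-05, adjusted p = 0.578 with an estimated correlation), with Kcnq1 2.49-fold and Kcnh2 2.37-fold lower. No respiratory chain gene was called (0 of 41 and 0 over the list alone in limma), though the list's median was -0.47 (camera adjusted p = 9.24e-11, adjusted p = 0.644 with an estimated correlation). Fatty acid oxidation genes fell in 5 of 28 (21 over the list alone, adjusted p = 2.88e-09, adjusted p = 0.621 with an estimated correlation). Of fibroblast markers 4 of 15 rose and 1 fell (5 and 1 over the list alone, adjusted p = 0.00873, adjusted p = 0.687 with an estimated correlation), with Col1a1 5.77-fold higher and Clec3b 3.57-fold lower. Without replicate 2 the calls of Rcan1, Thbs1, Kcnq1, Col1a1 and Clec3b ended (limma adjusted p = 0.0572, 0.0884, 0.0954, 0.135 and 0.111). The count of calls was 1288 in a fit on only the groups compared and 2074 without the 6 arrays in doubt. None of these 6 belongs to this comparison, so only the shared spread changed. Without 1 of the MKK3bE arrays it was 203 (replicate 1) or 132 (replicate 2), and without 1 control 428 (replicate 1) or 488 (replicate 4).

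Late MKK3bE hearts had higher hypertrophy markers, matrix and fibroblast genes than controls, and lower Map2k6. Myh7, the slow myosin heavy chain of the fetal and stressed heart, was 3.16-fold higher (log2 change 1.66, SE 0.35, limma adjusted p = 0.00386), at 190542 ± 19075 (SD, n = 5) against 63823 ± 25549 (SD, n = 6). Vgll2, a cofactor of muscle gene transcription, was 13.3-fold higher (log2 change 3.74, SE 0.50, adjusted p = 4.45e-05). Pla2g5, a secreted phospholipase, was 11.2-fold lower (log2 change -3.48, SE 0.29, adjusted p = 1.21e-08). Map2k6 was 5.72-fold lower (adjusted p = 0.000209). The brightest probe set of Mapk14 was 1.77-fold lower (log2 change -0.82, adjusted p = 1.65e-05), while its other 5 probe sets stood at -0.38 to 0.33. In all 1319 genes were called, 639 higher and 680 lower, and 324 changed at least 2-fold.

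The largest rise was again Esr1 (6.46 on the log2 scale, 7.13 without control female 2), followed by Mfap4, Vgll2, Shisa3, Nmrk2, Muc15, Krt18, Cilp, Syndig1 and Maoa. Maoa, which breaks down monoamines, was 5.76-fold higher. The largest falls were Pla2g5, Mylk4, Ces1d, Lgi1, Map2k6, Cenpf, Mfsd4a, Rasl10b, Mrgprh and Slc36a2. Hypertrophy marker genes rose in 8 of 11 members (10 adjusted over the list alone, camera adjusted p = 6.68e-08, adjusted p = 0.37 with an estimated correlation), with Fhl1 2.41-fold and Ankrd1 2.22-fold higher. Heat shock protein genes rose in 4 of 18 (9 rose and 2 fell over the list alone, adjusted p = 6.29e-05, adjusted p = 0.496 with an estimated correlation), with Hspa1b 4.12-fold and Hspa1a 3.84-fold higher. Extracellular matrix and fibrosis genes rose in 12 of 33 (19 over the list alone, adjusted p = 1.01e-10, adjusted p = 0.621 with an estimated correlation), among them Ltbp2 at 5.11-fold. Fibroblast markers rose in 6 of 15 (9 over the list alone, adjusted p = 7.86e-06, adjusted p = 0.578 with an estimated correlation), with Mfap5 3.24-fold and Pi16 2.89-fold higher. Fatty acid oxidation genes fell in 8 of 28 (12 over the list alone, adjusted p = 8.37e-07, adjusted p = 0.687 with an estimated correlation). The calls of Ltbp2 (log2 change 2.10, limma adjusted p = 0.0549), Syndig1 (2.21, 0.104) and Mrgprh (-2.14, 0.0508) ended without female late replicate 2, and that of Lgi1 without replicate 3 (-1.85, 0.122). The count of calls was 2262 in a fit on only the groups compared and 2581 without the 6 arrays in doubt, none of which belongs to this comparison. It was 541 without female late replicate 3, 564 without female late replicate 2 and 818 without male late replicate 2.

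**Figure D3:**
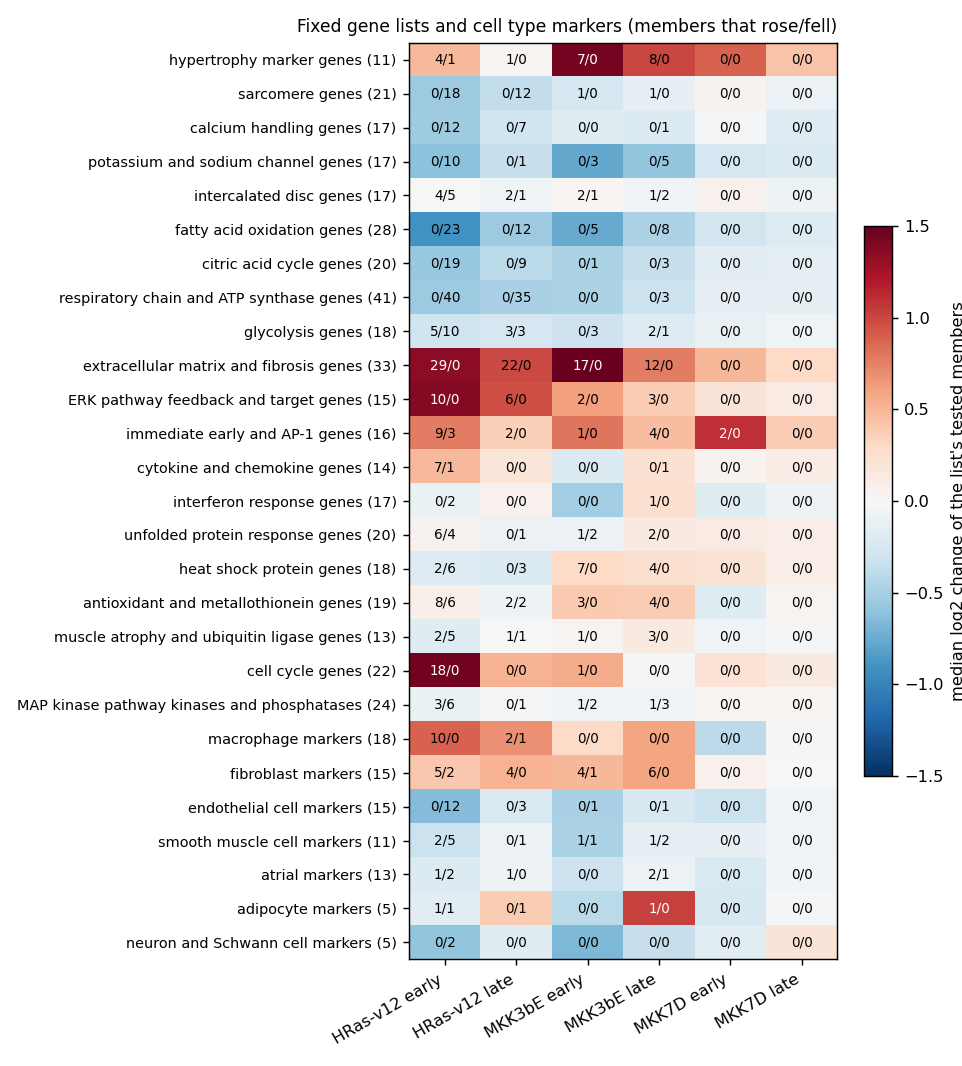
Median log2 change of the tested members of 27 fixed gene lists and cell type marker lists (colour) in the 6 comparisons against control, with the members called higher and lower written as rose/fell and the members tested in brackets. Respiratory chain genes fell in 40 of 41 members early and 35 of 41 late in HRas-v12, and hypertrophy markers rose in 7 and 8 of 11 in MKK3bE.

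Between late and early female MKK3bE hearts, 2 arrays against 2, Armh4 alone was called. It was 5.53-fold lower late (log2 change -2.47, SE 0.40, limma adjusted p = 0.0182), and 766 genes had an unadjusted p under 0.05. Armh4 was also the 1 gene whose late MKK3bE change differed between the sexes (3.09 more in males on the log2 scale, SE 0.49, adjusted p = 0.0129). Armh4 was named after its values were seen, and 587 genes had an unadjusted p under 0.05 between the sexes. Other fits gave 0 to 25 genes between the times, with 0 without female late replicate 3, 3 and 7 without female early replicates 1 and 2, and 5 without female late replicate 2. For the sexes they gave 0 without female late replicate 3, male late replicate 2, control female 4 or control male 2, and 2 without female late replicate 2 or control male 1.

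Early MKK7D hearts changed few genes at this threshold, with rises of Bhlhe40, Fosl2 and Nr1d1 and a fall of Alad. Bhlhe40, a repressor of the circadian clock, was 3.38-fold higher (log2 change 1.76, SE 0.24, limma adjusted p = 0.000394), at 21073 ± 2466 (SD, n = 3) against 6200 ± 410 (SD, n = 3). Fosl2, a part of the AP-1 transcription factor that JNK acts on, was 3.43-fold higher (log2 change 1.78, SE 0.33, adjusted p = 0.0177), and 1.59 without control replicate 3, where the call ended (adjusted p = 0.128). Nr1d1, a clock repressor, was 3.86-fold higher (log2 change 1.95, SE 0.27, adjusted p = 0.000394). Alad, an enzyme of heme synthesis, was 4.97-fold lower (log2 change -2.31, SE 0.36, adjusted p = 0.00331). Of 12626 genes 17 were called, 11 higher and 6 lower.

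Of the 17 genes called, 16 were named under the rule, and a further called rise was not. The other rises named were Otud1, Nova1, Btg2, Ier5, Lnx2, Trim35 and Slk, and the other falls Mgst1, Hdhd3, Cry1, Snn and Nkx2-5. Nkx2-5, a transcription factor of heart muscle identity, was 1.57-fold lower. Without control replicate 3 all 12 of these calls ended (adjusted p from 0.109 to 0.237). A further probe set of Snn stood at 0.22 on the log2 scale. Nr1d1 read 1489 to 2601 in the early MKK7D controls and 7229 to 8008 in the transgenic arrays, against 5536 to 7196 in the shared controls. Immediate early and AP-1 genes rose in 2 of 16 members over all genes and in 11 adjusted over the list alone (median log2 change 1.10, camera adjusted p = 9.66e-12, adjusted p = 0.37 with an estimated correlation). No hypertrophy marker was called over all genes, while 8 of 11 rose and 1 fell over the list alone (adjusted p = 3.89e-06, adjusted p = 0.496 with an estimated correlation). Of extracellular matrix and fibrosis genes 0 of 33 were called and 3 rose over the list alone (adjusted p = 1.25e-05, adjusted p = 0.715 with an estimated correlation). The other 8 lists called had 0 members called in limma over all genes. Heat shock genes had a median of 0.20 (3 higher over the list alone, adjusted p = 0.00156) and intercalated disc genes of 0.07 (2 higher over the list alone, adjusted p = 0.0255), both with an adjusted p = 0.578 with an estimated correlation. The 6 others had 0 members called over the list alone too. Fatty acid oxidation genes had a median of -0.27 (adjusted p = 0.000327), citric acid cycle genes of -0.16 (0.00996), channel genes of -0.25 (0.0384) and macrophage markers of -0.39 (0.00645), all 4 with an adjusted p = 0.715 with an estimated correlation. Respiratory chain genes had a median of -0.12 (adjusted p = 0.00303, adjusted p = 0.765 with an estimated correlation) and endothelial cell markers of -0.32 (adjusted p = 0.00262, adjusted p = 0.654 with an estimated correlation). Tgfb2 stood at 2.76 (SE 0.66, adjusted p = 0.0669) and Ccn2 at 2.06 (SE 0.50, adjusted p = 0.0669) on the log2 scale. The count of calls was 372 in a fit on only the groups compared and 123 without the arrays in doubt. Without 1 control it was 3 (replicate 1, the array with male markers), 102 (replicate 2) or 5 (replicate 3), and without 1 transgenic array 5 (replicate 7), 6 (replicate 5) or 7 (replicate 6).

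Late MKK7D hearts could not be told from their labelled controls gene by gene. Limma called 0 genes, with 643 at an unadjusted p under 0.05 and a smallest adjusted p of 0.136. No member of any list was called over all genes, and 1 heat shock gene rose over that list alone, Hspa1a, at 1.63 on the log2 scale (SE 0.45, adjusted p = 0.536 over all genes). Camera called 11 of 27 lists, 4 up and 7 down, and 0 with an estimated correlation. As a list, hypertrophy markers had a median of 0.43 (camera adjusted p = 0.0196, adjusted p = 0.654 with an estimated correlation) and heat shock genes of 0.10 (adjusted p = 0.00273, adjusted p = 0.578 with an estimated correlation). The arrays labelled control replicate 8 and control replicate 9 had Esr1 at the transgenic level. Sarcomere genes had a median of -0.09 (adjusted p = 0.0196, adjusted p = 0.715 with an estimated correlation) that turned to 0.02 under quantile normalization. With these 2 controls and the other doubted arrays left out, 428 genes were called, 280 higher and 148 lower, against the lone control replicate 10, which is then assumed to vary like the other groups. In that fit extracellular matrix genes rose in 17 of 33 members and hypertrophy markers in 4 of 11. In the fits that left out a single array the count was 1 without control replicate 8, 9 or 10 or transgenic replicate 13.

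The change of MKK7D hearts differed between late and early in Bhlhe40 (-2.01 on the log2 scale, SE 0.33, limma adjusted p = 0.0225) and Arrdc3 (-1.26, SE 0.22, adjusted p = 0.0225). Mean Bhlhe40 signals were 21073 early and 18744 late in transgenic arrays and 6200 early and 22480 late in controls. Late controls 8 and 9, with the Esr1 signal, read 23799 and 23118. Late control 10, without it, read 20522, so the high late control level was not confined to the arrays with that signal. Both genes were named after their values were seen, and 673 genes had an unadjusted p under 0.05. The count was 0 without control early replicate 1, late controls 8 or 9, early transgenic replicates 6 or 7, or late transgenic replicates 13 or 15. It was 4 without control early replicate 2 and 9 without late control 10.

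Late HRas-v12 and late MKK3bE hearts were compared directly, since both share their controls. Heat shock genes were lower in HRas-v12 in 11 of 18 members (14 adjusted over the list alone, camera adjusted p = 2.73e-15), and this list alone stayed called with an estimated correlation (adjusted p = 0.0191). Hspa1a was 5.07-fold lower in HRas-v12 (log2 change -2.34, SE 0.33, limma adjusted p = 0.000126). Vgll2 was 9.95-fold and Myot, a Z-disc protein gene, 6.64-fold lower in HRas-v12, and 5 of 11 hypertrophy markers were lower (6 over the list alone, adjusted p = 2.26e-09, adjusted p = 0.37 with an estimated correlation). Pla2g5 was 8.67-fold, Map2k6 5.21-fold and Gnai1 3.49-fold higher in HRas-v12. Pla2g5 and Map2k6 were also among the largest falls of late MKK3bE hearts against control. The HRas-v12 means include male late replicates 1 and 4, at the control level of the score (0.02 and -0.03). In all 499 genes differed, 242 higher and 257 lower in HRas-v12. The count was 181 in a fit on only these groups, 814 without the 6 arrays in doubt (1 male HRas-v12 array left), 175 without MKK3bE female late replicate 3 and 854 without HRas-v12 male late replicate 3.

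**Figure D4:**
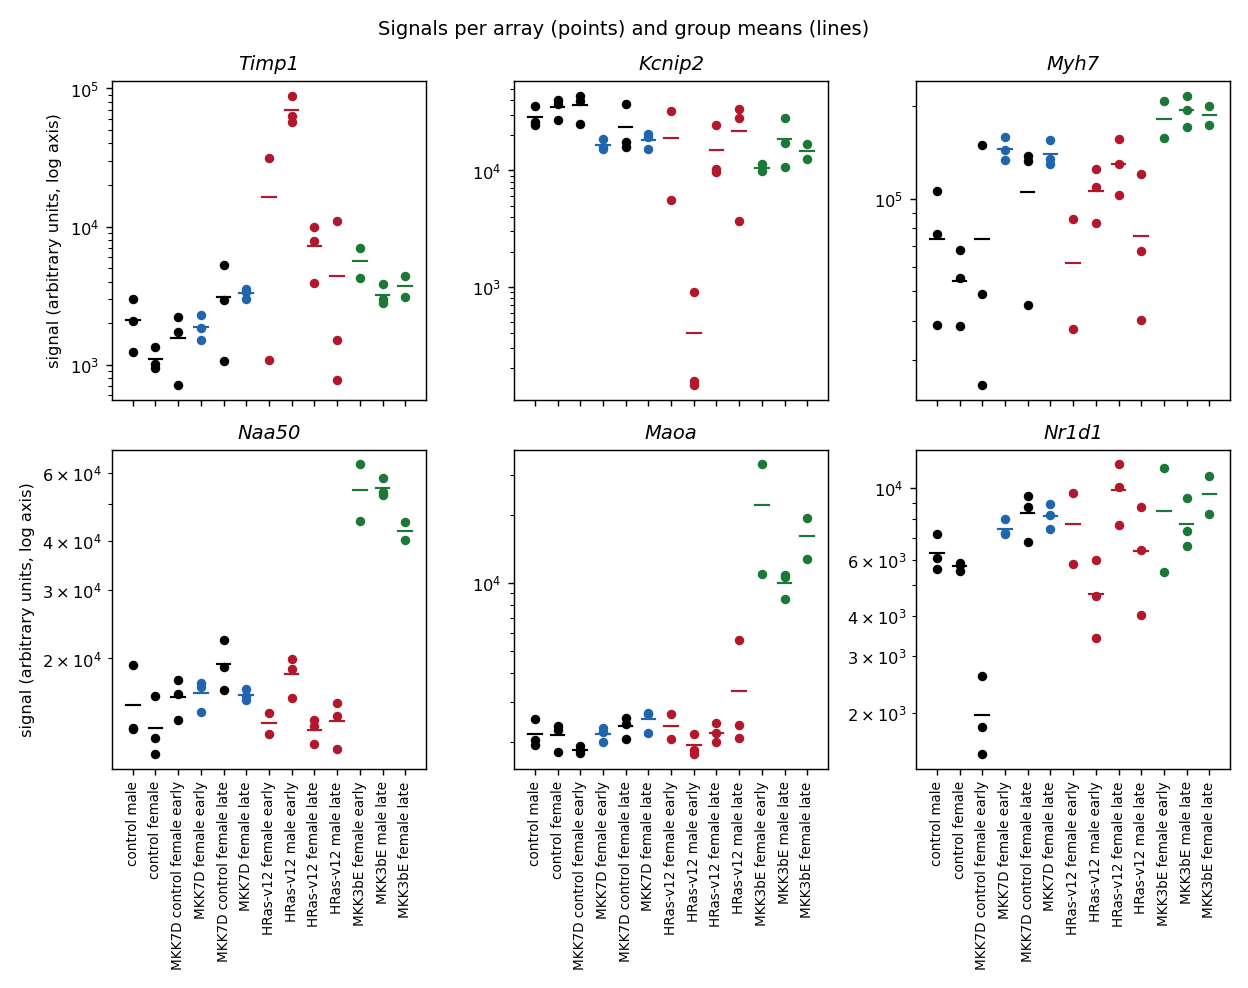
Signals of 6 genes on each of the 36 arrays (points, arbitrary intensity units, log axis) with the arithmetic mean of each group (line), with controls in black, HRas-v12 in red, MKK3bE in green and MKK7D in blue. Naa50 lay at 40342 or above in the 7 MKK3bE arrays and at 22290 or below in the other 29 arrays.

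The late changes of the lines were then set against that of MKK7D, each line with its own controls, in females. MKK3bE differed from MKK7D in 8 genes, with Maoa (2.77 on the log2 scale, SE 0.43, limma adjusted p = 0.00376), Naa50 (1.94, SE 0.23, adjusted p = 6.78e-05), Usf3 and Strap higher and Hddc3, Pla2g5, Fah and Man2a2 lower. The count was 1 without MKK3bE female late replicate 3, 2 without late MKK7D control 8 or 9 or transgenic replicate 13 or 14, 3 without control female 4 and 23 without late MKK7D control 10. HRas-v12 differed from MKK7D in 0 genes in limma, with 1694 at an unadjusted p under 0.05. The count was 51 in a fit on only these groups, 98 without the arrays in doubt and 3 without HRas-v12 female late replicate 2. As a list, extracellular matrix genes had a median difference of 1.30 (0 of 33 called over all genes, 19 higher over the list alone, camera adjusted p = 1.07e-13, adjusted p = 0.591 with an estimated correlation). In both comparisons 2 of the MKK7D control arrays carried the Esr1 signal of the transgenic arrays.

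HRas-v12 and MKK3bE hearts changed many of the same genes. Early, 199 genes were higher in both lines and 229 lower in both, and 21 went opposite ways. Independent lists would share 66.2 and 65.7, and unchanged groups against the same controls shared 0 in 100 simulations. Unchanged groups leave few genes to call, so that 0 does not measure what shared controls add to the overlap of changed groups. The log2 changes correlated across genes with r = 0.59 (0.32 simulated, covariance 0.191 against 0.0277 simulated), where genes are not independent replicates. No value with split controls was made for the early pair, which shares 3 female controls. Late, 170 were higher and 156 lower in both (31 and 31.7 for independent lists), with r = 0.64 (0.5 simulated, covariance 0.102 against 0.0255). With the controls split between the lines, 1.5 and 1.22 genes were shared on average and r was 0.44. Each comparison with split controls, here and below, had only 3 control arrays. Calls lost to fewer controls and the effect of shared controls therefore cannot be told apart. Within HRas-v12, 397 genes were higher and 433 lower at both times (92.4 and 110 for independent lists, r = 0.73 against 0.49 simulated, covariance 0.153 against 0.026, and 13.3 and 7.06 genes shared with split controls). Within MKK3bE, 297 were higher and 212 lower at both times (22.2 and 18.9, r = 0.79 against 0.33, covariance 0.197 against 0.0273). Early MKK7D, with its own controls, shared 2 higher genes with early HRas-v12 (1.66 for independent lists, with 0 lower against 1.12 and 1 opposite). It shared 3 higher genes with early MKK3bE (0.382) and 5 higher and 4 lower with late MKK3bE (0.557 and 0.323), with 0 opposite in both. Without the arrays in doubt, HRas-v12 and MKK3bE shared 1511 genes early and 103 late, and early MKK7D shared 74 with early HRas-v12 and 76 with early MKK3bE.

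Between male and female control hearts limma called 0 genes, with 1148 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0502. Xist, the transcript that silences an X chromosome in females, differed by -2.46 on the log2 scale. Eif2s3y read 4326 to 4780 in control males and 12 to 156 in control females but was not among the genes tested. The spread of Xist and Uty also drew on MKK7D control female early replicate 1, an array with male markers (Xist 2316, Uty 2567). The 0 calls are therefore no statement that the sexes do not differ. Other fits gave up to 29 genes. Without 1 array the count was 61 (control female 2), 2 (control female 4) or 1 (control male 1 or 5).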

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

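The tests of the 3 patterns in this part were chosen only after the results were seen, while the tests of differences between groups and the other splits of the arrays were planned.

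The late MKK7D controls held 2 arrays, labelled control replicate 8 and replicate 9, with Esr1 signals of 106402 and 91291. A swap with transgenic arrays of the same time was argued against, since the lowest of these read 88303 and a swapped array would lie near the shared controls, at 7943 or less. Higher expression of the Esr1 gene itself stays open, since the other 2 Esr1 probe sets were dim in all arrays, at most 521 in these and up to 1296 in others. Whether the 2 animals carry the driver stays open beyond that signal, since the score tried (0.29 or more on the genes of early male HRas-v12 hearts, at most 0.14 in other controls) did not follow Esr1 in HRas-v12 arrays, with -0.03 at 155949 and 0.73 at 1327. Whether they carry MKK7D cannot be told apart with no signal of the transgene (hypertrophy marker mean 15.66 against a lowest transgenic value of 15.59).

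On the genes of early male HRas-v12 hearts 3 HRas-v12 arrays scored like controls, labelled female early replicate 3 (0.01), male late replicate 1 (0.02) and male late replicate 4 (-0.03), where the other HRas-v12 arrays scored 0.24 to 1.13. A swap with shared controls was argued against only for female HRas-v12 hearts that responded, since no shared control scored above 0.04. For males the score does not decide this, since its genes were chosen for a difference from the control males. The mean of each sex's shared controls is the reference, so their average score is fixed. The score cannot decide on hearts that did not respond, since male late replicate 4 scored like a control with a bright Esr1 signal. Animals without the driver could account for the first 2 arrays, whose Esr1 read at most 2915, but not for male late replicate 4 at 155949. The array labelled male late replicate 3 scored 0.73 at an Esr1 signal of 1327, which a missing driver leaves unexplained. The early HRas-v12 change differed between the sexes in 139 genes by a test of the difference, and a sex difference cannot be told apart from the state of single arrays, with 4 genes without female early replicate 3, 1393 without female early replicate 1, 81 without the 6 arrays in doubt and 29 in a fit on only the groups compared.

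Naa50 and Usf3, neighbours on chromosome 16 singled out after their values were seen, were higher in MKK3bE hearts at both times (Naa50 2.02 early and 1.78 late, Usf3 0.76 and 0.87 on the log2 scale). A response shared with HRas-v12 hearts was argued against for Naa50, which was lower there by -1.85 on the log2 scale (limma adjusted p = 2.97e-11). Chance neighbours were argued against for the set of 297 genes higher at both times, which held 17 neighbouring pairs against a mean of 6.97 in 1000 random orders, with 1 order giving as many. Random orders hold pairs too, so this does not decide whether Naa50 and Usf3 are a chance pair. The place where the transgene sits in the genome could raise both genes, and this cannot be told apart from a response to MKK3bE, since a single MKK3bE line was measured (lowest MKK3bE signal of Naa50 40342 and of Usf3 6519, highest of other arrays 22290 and 6410). The nearest genes tested on either side were not called, Atp6v1a at 0.18 early and 0.16 late (adjusted p = 0.582 and 0.418) and Spice1 at 0.60 and 0.40 (0.303 and 0.279).

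Other differences between groups came out of tests of the difference itself. Late and early HRas-v12 hearts differed in 1463 genes, where 11 of 100 splits gave as many and the highest other gave 3806, so chance could not be excluded and the splits point to a structure of the samples. Late and early MKK3bE hearts differed in 1 gene, Armh4. The MKK7D change differed between the times in 2 genes, where 18 of 100 splits gave as many and the highest other gave 107, so chance could not be excluded and a structure of the samples shows here too. Late HRas-v12 and late MKK3bE hearts differed in 499 genes. Of the 100 splits run, of 200 possible, only the real 1 gave as many. The highest other gave 186, so chance was argued against. The late MKK3bE change differed from that of MKK7D in 8 genes, and from female to male in 1 gene, Armh4.

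For the comparisons against control, early HRas-v12 had 4267 genes and the highest other split 3994. Only the real 1 of the 100 splits run, of 200 possible, gave as many, so chance was argued against. With another split this near, chance is not taken as excluded, since the splits not run could hold a higher count. Late HRas-v12 had 1202 genes, and 4 of 100 splits, the real 1 included, gave as many, up to 2003. That share lies under 0.05, but splits above the real count point to a structure of the samples, so chance is not taken as excluded here. The count was 0 in a fit on only the groups compared (limma, 2668 at an unadjusted p under 0.05) and 132 without male late replicate 3. Late MKK3bE had 1319 genes and the highest other split 458, at 1 of 100. The 10 splits of the MKK7D arrays are too few for a share under 0.05, with 17 genes early (1 split as large, highest other 2). Late MKK7D had 0 genes in limma and 643 at an unadjusted p under 0.05 (highest other 0, so all 10 splits were as large). The 10 splits of the control arrays by sex are also too few, with 0 genes in limma, 1148 at an unadjusted p under 0.05 and a highest other of 24. The late changes of HRas-v12 and MKK7D differed in 0 genes in limma (1694 at an unadjusted p under 0.05), with up to 815 in other splits. The late HRas-v12 change differed between the sexes in 0 genes in limma (988 at an unadjusted p under 0.05), with up to 984 in other splits. Each of the 100 splits must reach a count of 0, so these 2 tests say nothing on chance, while splits that call so many genes point to a structure of the samples.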

How the results depend on the processing

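The fit without the 6 arrays in doubt and the pseudocount of 160 were chosen only after the results were seen, and the other alternatives were planned. In the comparisons against control, no named gene that was called turned its direction under the alternatives run for it, and the genes named in other comparisons were not rerun. Of the named genes called, 89 of 113 in early HRas-v12, 19 of 79 in late HRas-v12, 11 of 65 in early MKK3bE, 40 of 86 in late MKK3bE and 3 of 16 in early MKK7D stayed called whichever array was left out. In the same order, quantile normalization ended the calls of 1, 25, 1, 8 and 1 of the named genes, no filter of 1, 13, 3, 15 and 5, a fit on only the groups compared of 5, 79, 2, 4 and 0, and the fit without the 6 arrays in doubt of 0, 56, 0, 0 and 2. Dim signals limit what these arrays show, since no detection calls were used. Counts not given here stayed within 1.5 times the reported count, and the cause of a moved count was not tested unless said.

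With all probe sets, which raises the number of tests, the counts were 7620 for early HRas-v12, 2636 for late HRas-v12, 39 for early MKK7D, 2442 for late against early HRas-v12, 3 for late against early MKK3bE and 1 for late minus early MKK7D. They were 776 for late HRas-v12 against late MKK3bE, 8 for the late difference of HRas-v12 and MKK7D, 19 for control sex and 3 for the sex difference of late HRas-v12. In a fit on only the groups compared, the counts were 0 for late HRas-v12 in limma (2668 at an unadjusted p under 0.05), 1288 for early and 2262 for late MKK3bE, 372 for early MKK7D, 49 for late against early HRas-v12 and 25 for late against early MKK3bE. They were 5 for late minus early MKK7D, 181 for late HRas-v12 against late MKK3bE, 51 for the late difference of HRas-v12 and MKK7D, 10 for control sex and 29 for the sex difference of early HRas-v12.

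Without the 6 arrays in doubt, the counts were 157 for late HRas-v12, 2074 for early and 2581 for late MKK3bE, 123 for early and 428 for late MKK7D, 3291 for late against early HRas-v12, 16 for late against early MKK3bE and 4 for late minus early MKK7D. They were 814 for late HRas-v12 against late MKK3bE, 98 for the late difference of HRas-v12 and MKK7D, 29 for control sex, and 81 early and 476 late for the sex difference of HRas-v12. Genes shared in direction were then 1511 for HRas-v12 and MKK3bE early and 103 late, 74 for early HRas-v12 and early MKK7D, and 76 for early MKK3bE and early MKK7D. That fit leaves 1 late MKK7D control, 1 early female HRas-v12 array and 1 late male HRas-v12 array (replicate 4, which scored -0.03), each assumed to vary like the other groups. Control sex gave 4 genes with quantile normalization, 7 with a pseudocount of 1, 2 with no filter and 8 with a pseudocount of 160, which gave 9 for late against early MKK3bE. With an estimated correlation, 1 of 90 gene list calls and 0 of 17 cell type marker calls of camera remained. Quantile normalization kept 90 of these 107 calls and turned the direction of 2, and the fit without the 6 arrays in doubt kept 88 and turned 6.

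Replicate numbers did not pair the arrays. Of 23 pairs of arrays with the same number, 4 correlated over 0.1 (median -0.01, range -0.34 to 0.12), against a median of -0.01 in 88 pairs with different numbers. With a replicate block the counts were 1637 for early and 0 for late HRas-v12 in limma (2551 at an unadjusted p under 0.05), 155 for early and 216 for late MKK3bE, 46 for late against early HRas-v12, 0 for late against early MKK3bE (485 at that p), and 134 for late HRas-v12 against late MKK3bE. They were 0 for the sex differences of early HRas-v12 (1076 at that p) and of late MKK3bE (356). The block ended the calls of 20 of the 113 named genes called in early and 79 of 79 in late HRas-v12, and of 38 of 65 in early and 54 of 86 in late MKK3bE. No paired analysis was possible because of missing shared numbers for the MKK7D groups.

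Leaving out 1 array at a time gave 1571 to 4864 genes for early HRas-v12 and 132 to 2507 for late HRas-v12. It gave 132 to 577 for early MKK3bE, 541 to 1179 for late MKK3bE, 3 to 102 for early MKK7D and 0 to 1 for late MKK7D. Between times it gave 338 to 2716 for HRas-v12, 0 to 7 for MKK3bE and 0 to 9 for MKK7D. Between lines it gave 175 to 854 for late HRas-v12 against late MKK3bE, 0 to 3 for HRas-v12 and MKK7D, and 1 to 23 for MKK3bE and MKK7D. For the sexes it gave 0 to 61 in controls, 4 to 1393 in early HRas-v12, 0 to 5 in late HRas-v12 and 0 to 2 in late MKK3bE.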

Other observations

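The genes named in the last paragraph of this part were chosen only after their values were seen, and the lists were planned. In early HRas-v12 hearts 7 of 14 cytokine and chemokine genes rose and 1 fell (7 and 1 adjusted over the list alone), though the list as a whole was not called (camera adjusted p = 0.114). Ccl7, which attracts monocytes, was 3.68-fold higher (limma adjusted p = 0.000456), and Cxcl12 was 1.60-fold lower (adjusted p = 0.00125). Of 16 immediate early and AP-1 genes 9 rose and 3 fell (9 and 4 over the list alone, camera adjusted p = 0.0195, adjusted p = 0.715 with an estimated correlation), with Btg2 2.65-fold higher and Dusp1 1.77-fold lower. Antioxidant and metallothionein genes went both ways, 8 of 19 up and 6 down (8 and 6 over the list alone, adjusted p = 0.534).

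In MKK3bE hearts 3 of these 19 antioxidant genes rose early (3 over the list alone, camera adjusted p = 0.0149, adjusted p = 0.578 with an estimated correlation) and 4 late (6 rose and 2 fell over the list alone, adjusted p = 0.00546, adjusted p = 0.578 with an estimated correlation). Gpx3, a secreted glutathione peroxidase, was 3.18-fold higher early (limma adjusted p = 0.0115) and 2.54-fold late (adjusted p = 0.00195). Txnrd1, a thioredoxin reductase, was 2.02-fold higher early (adjusted p = 0.00185) and 1.42-fold late (adjusted p = 0.00926). Immediate early and AP-1 genes rose in 4 of 16 members late (6 over the list alone, camera adjusted p = 0.000206, adjusted p = 0.591 with an estimated correlation), with Nr4a1 2.38-fold higher.

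Nr1d1 and Bhlhe40, genes of the circadian clock, read lower in the 3 early MKK7D controls (1489 to 2601 and 5809 to 6627) than in the other 33 arrays (at least 3434 and 7498). Other clock genes overlapped with further groups. Dbp read 9211 to 12031 in the early MKK7D controls, 20580 to 26797 in the early MKK7D transgenic arrays, 7811 to 43690 in the shared controls and 3333 to 10624 in early male HRas-v12 hearts. Ciart read 750 to 1085, 2352 to 3012, 902 to 4861 and 457 to 1355 in the same order. Nfil3 read 3172 to 5379 in the early MKK7D controls, 1622 to 1906 in the early and 2725 to 3537 in the late MKK7D transgenic arrays. The labels give no time of day for any array. Alad and Hdhd3, neighbours on chromosome 4, read 3452 to 4938 and 554 to 860 in early MKK7D hearts, against 16529 to 21625 and 1751 to 2534 in their controls. Low readings were not confined to these hearts. Late MKK7D transgenic arrays read 3217 to 7757 and 586 to 1515, and late MKK7D controls 7432 to 10957 and 1279 to 1420. Late female HRas-v12 arrays read 3995 to 10369 and 927 to 1594.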
